A study of Homo sapiens with 12 samples.

How the data were processed

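RNA was measured in 12 libraries of A2058 melanoma cells, 3 in each of 4 groups. Per the labels' protocols, cells were transduced with lentivirus made from an empty or a MITF-carrying vector and selected with puromycin, or transfected with siRNA by lipofection for 48 hours. Stranded total RNA libraries were sequenced as paired-end reads of 76 bases. The submitters' processing notes name bcl2fastq 2.18.0, STAR 2.6.0, SAMtools 1.10 and featureCounts 1.6.3 and the genome build hg19. The settings of these tools, including strand handling and the treatment of reads that fit several genes, are not given in the sources used here. Genes of families with near-identical members, such as HLA and histone genes, and overlapping genes are therefore uncertain as single genes.

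The values deposited by the authors are whole-number counts per gene and library, not normalized, in 1 table of 26364 genes identified by symbol. 0 rows had no gene and 0 columns of the table went unused. A second file, with the names and checksums of the read files, was not used here. 5147 genes had no count in any library. For 23629 symbols a match was found in the RefSeq gene table of assembly GRCh38.p14. As that assembly is not the authors' build, it was used only for gene type and chromosome name, and no coordinates are given.

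Total counts ran from 7427637 to 23938392 per library. A count of 0 allows, at a floor of 3 counts, up to 0.404 CPM in the shallowest and 0.125 CPM in the deepest library. Folds against a group with 0 counts in all its libraries are lower bounds against 3 counts over the group. With 1 to 3 counts in a group the ratio is given with an exact 95% binomial counting interval. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. With such genes at their bound the list medians moved by under 0.1, except the fibroblast list between the controls (0.36 and 0.20).

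Genes were kept by edgeR's filterByExpr with its minimum count of 10 (14297 genes, at least 99.9% of each library's counts). Libraries were scaled by TMM, and all 12 entered 1 fit of group means by the edgeR quasi-likelihood method with robust estimation (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Tests were made for MITF overexpression minus empty vector, MITF siRNA minus scrambled siRNA, scrambled siRNA minus empty vector, and the difference between the responses of the first 2. Benjamini-Hochberg adjusted p-values under 0.05 were called. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values are TMM-scaled.

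37 gene lists on melanocyte differentiation, melanoma states, matrix and adhesion, signalling, the cell cycle, metabolism, stress, RNA quality and other cell types were fixed from general knowledge. 35 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and p-values were adjusted over the lists. Fry's p tests whether a list's genes move one way on balance. The named genes are MITF, the 10 largest rises and 10 largest falls per comparison, and up to 4 called members of each list by adjusted p (2 by abundance where none was called), of which the text gives a part; 1 gene that the rule names is not reported here. CD74, HLA-DOB, HLA-DPB1 and SNAI2 were added after the data were examined. The large changes come from called genes with a mean of at least 1 log2 CPM and no overlap between the libraries compared, without pseudogenes, placeholder names and Y-linked genes. For the difference of responses the rule takes 5 in each direction with no condition on overlap. The gene lists, the tests named so far and all alternatives except the exchange of control groups were chosen before the data were examined. The neighbour windows and the group of HLA class II genes were chosen afterwards.

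The steps were tested on simulated data with the real means, library sizes and dispersions and 50 genes changed at each of 4 fold sizes. Rises and falls were equal in number there. Far fewer genes were changed than were called in the real comparisons (35.4% to 59.4% of tested genes). The shares recovered and the false calls therefore describe that setting and not these comparisons. Over 14120 simulated genes for overexpression, the test recovered 56% of those changed 1.25-fold, 86% of those changed 1.50-fold, 92% of those changed 2-fold, 98% of those changed 4-fold, with 11 of 177 calls false. Over 14112 genes for MITF siRNA it recovered 64% of those changed 1.25-fold, 86% of those changed 1.50-fold, 82% of those changed 2-fold, 100% of those changed 4-fold, with 13 of 179 calls false. For the control groups (14121 genes) it recovered 58% of those changed 1.25-fold, 80% of those changed 1.50-fold, 74% of those changed 2-fold, 98% of those changed 4-fold, with 10 of 165 calls false. For the difference of responses (14129 genes) it recovered 34% of those changed 1.25-fold, 74% of those changed 1.50-fold, 72% of those changed 2-fold, 98% of those changed 4-fold, with 7 of 146 calls false.

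The alternatives tried were DESeq2 1.42.0 and limma-voom in place of the test, DESeq2 size factors, upper-quartile scaling, library totals and library sizes without the 20 most abundant genes, no filter on low counts or at least 1 CPM in 3 libraries, only the libraries compared, the replicate number as a block, stricter thresholds, other list tests, and leaving out each library. Runs of neighbouring genes were sought among 11454 genes of at least 1 log2 CPM with a chromosome name (92.6% of those at that level), as medians over 30 genes in the order of the table, against 1000 shuffles of the gene order. Runs and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.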

Results

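The data are gene counts from bulk RNA sequencing of A2058, an established human melanoma cell line, in which the level of MITF was moved in both directions. MITF is the transcription factor that drives melanocyte differentiation and pigment gene expression. The 12 libraries fell into 4 groups of 3. Cells were transduced with an empty lentiviral vector or with the same vector carrying MITF. Others were transfected with a siRNA against MITF for 48 hours or with a scrambled siRNA. Total counts were 14500191, 7427637 and 10005404 in the empty vector libraries and 21246063, 19665547 and 14671314 in the MITF overexpression libraries. They were 17870695, 19746531 and 23938392 in the MITF siRNA libraries and 13100703, 14287537 and 13618880 in the scrambled siRNA libraries. The table held 26364 genes, of which 14297 passed the filter on low counts and were tested. Within each group the libraries correlated at Pearson's r of 0.991 or more over genes, and no pair of libraries was identical. The labels call the libraries of a group biological replicates and independent, chosen after a check of RNA integrity. How separately they were cultured is not given in the sources used here, so the p-values measure the spread between these libraries.

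The first principal component of log2-scaled expression, with 61.3% of the variance, set the MITF overexpression libraries apart from the other 9. The second, with 17.0%, separated the empty vector libraries from both siRNA groups, and the third, with 6.98%, separated MITF siRNA from scrambled siRNA.

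The targeted gene moved in the labelled direction in both comparisons. MITF stood at 304 ± 6.75 CPM (mean ± SD, n = 3; CPM is the count scaled to library size) with the empty vector and 657 ± 23.3 CPM with the MITF vector, a 2.16-fold rise (log2 fold change 1.11 (SE 0.051), adjusted p = 4.06e-18, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, as for every adjusted p of a gene here). It stood at 467 ± 36.8 CPM with scrambled siRNA and 343 ± 21.4 CPM with MITF siRNA, 26.4% lower (log2 fold change -0.44 (SE 0.050), adjusted p = 2.84e-08). The single libraries gave 299, 311 and 301 CPM with the empty vector, 658, 679 and 633 with the MITF vector, 504, 465 and 431 with scrambled siRNA and 343, 322 and 365 with MITF siRNA. The control groups were not at the same level: MITF was 1.54-fold higher with scrambled siRNA than with the empty vector (adjusted p = 3.17e-11). The MITF siRNA libraries therefore still lay above the empty vector libraries, by a log2 difference of 0.18 (SE 0.051, adjusted p = 0.00545).

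**Figure D1:**
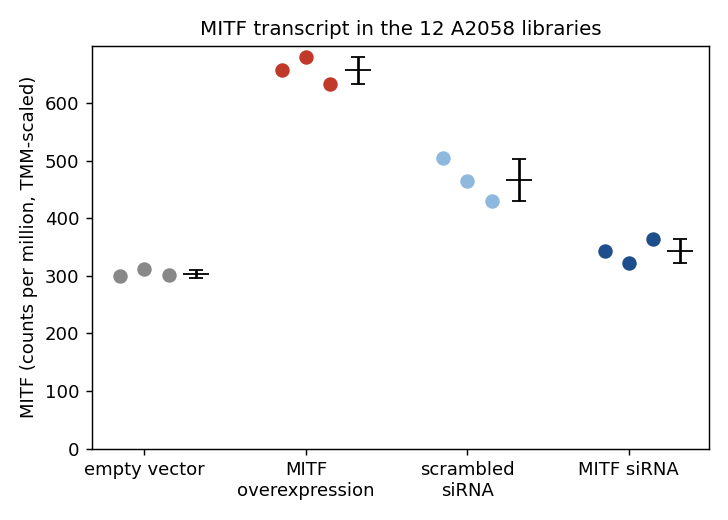
MITF in TMM-scaled CPM in each of the 12 libraries, 3 points per group, with the group mean and SD as a bar beside them. The MITF siRNA libraries lie below the scrambled siRNA libraries and above the empty vector libraries, and the MITF overexpression libraries are highest.

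The comparison of MITF overexpression with the empty vector asks what a raised MITF level does in these cells. Changes due to raised MITF cannot be told apart here from other differences of these libraries, in Y-linked genes and a chromosome 13 run, described below. Pigment genes rose and genes of the invasive, dedifferentiated melanoma state fell. MLANA, a melanosome protein and melanoma antigen, rose 8.47-fold (from 62.3 ± 3.45 to 525 ± 19.2 CPM, n = 3 per group, adjusted p = 2.53e-28). SLC45A2, a melanosomal transporter, rose 4.31-fold. Genes of cell adhesion, the extracellular matrix and inflammatory signalling fell together, among them VCAN, a large matrix proteoglycan, which fell 21.9-fold (adjusted p = 1.42e-24), and the cytokine gene IL6, which fell 11.3-fold. Most HLA class II genes fell, HLA-DRA and HLA-DQA1 to near 0.

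Medians of lists are log2 fold changes over their tested genes. Of 19 measured genes of the pigmentation and melanocyte differentiation list, 15 rose and 4 fell (median 1.03, camera adjusted p = 4.89e-19, adjusted p = 0.0344 with an estimated correlation). RAB38, a member of that list, rose (log2 fold change 1.32 (SE 0.065)), whereas TYRP1, an enzyme of melanin synthesis, fell (-1.26 (SE 0.051)). Among 28 other reported MITF targets, 24 rose and 2 fell (median 1.15, camera adjusted p = 1.16e-22, adjusted p = 0.0393 with an estimated correlation). Examples are the ceramidase gene ASAH1 (1.32 (SE 0.045)), ACP5 (1.90 (SE 0.086)), GYG2 (1.42 (SE 0.058)) and MYO1D (1.23 (SE 0.056)). The lysosome and autophagy list leaned the same way: 29 rose and 12 fell of 56 (median 0.15, camera adjusted p = 0.00353, adjusted p = 0.156 with an estimated correlation), with RRAGD, a GTPase of nutrient signalling, at 1.21 (SE 0.057) and the chloride transporter gene CLCN7 at 0.99 (SE 0.052). PPARGC1A, a regulator of mitochondrial genes, rose 3.96-fold, while the nuclear genes of oxidative phosphorylation (9 up and 10 down of 54, 9 and 9 adjusted over the list alone) were not called as a list (adjusted p = 0.731).

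None of 20 genes of the invasive state list rose and 17 fell (median -1.98, camera adjusted p = 1.72e-15, adjusted p = 0.0393 with an estimated correlation). They included FGF2 (-2.01 (SE 0.084)), NUAK1 (-1.89 (SE 0.11)), PLAUR (-1.96 (SE 0.10)) and the potassium channel gene KCNMA1, lower by 79.8-fold (95% counting interval 21.5 to 669.5); its fitted log2 value of -6.04 became -8.50 without MITF overexpression replicate 3. Of 43 genes of integrins, focal adhesion and the actin cytoskeleton, 3 rose and 38 fell (median -0.76, camera adjusted p = 1.57e-23, adjusted p = 0.0393 with an estimated correlation), as shown by ITGA1 (-1.62 (SE 0.047)), TPM2 (-1.39 (SE 0.048)) and ITGA6 (-1.36 (SE 0.048)). In the extracellular matrix list 8 rose and 21 fell of 35 (median -0.47, camera adjusted p = 8.27e-07, adjusted p = 0.0393 with an estimated correlation), with COL12A1 at -2.68 (SE 0.091) and SPARC at -1.06 (SE 0.047). Among 25 matrix remodelling enzymes and inhibitors, 1 rose and 21 fell (median -0.59, camera adjusted p = 8.52e-14, adjusted p = 0.0422 with an estimated correlation). MMP16 and LOXL3 were at -1.47 (SE 0.049) and -2.44 (SE 0.10), and the collagenase gene MMP1 fell 128-fold. The cadherin and epithelial-mesenchymal transition list had 5 up and 9 down of 16 tested (median -0.37, camera adjusted p = 7.83e-04, adjusted p = 0.0393 with an estimated correlation), with CDH2 (N-cadherin) at -1.66 (SE 0.054) and CLDN1 at -3.01 (SE 0.10).

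NF-kappaB and YAP target genes fell as well. In the NF-kappaB and cytokine list 1 rose and 24 fell (1 and 25 adjusted over the list alone) of 28 (median -1.36, camera adjusted p = 3.84e-19, adjusted p = 0.0393 with an estimated correlation), including BIRC3 (-2.23 (SE 0.072)) and CXCL2 (-2.78 (SE 0.11)). YAP and TEAD targets had 2 up and 20 down of 25 tested (median -0.78, camera adjusted p = 8.49e-09, adjusted p = 0.0433 with an estimated correlation), for example AJUBA at -1.31 (SE 0.087). The TGF-beta response list had 8 up and 16 down of 25 (median -0.41, camera adjusted p = 2.00e-05, adjusted p = 0.143 with an estimated correlation), with ID1 at -3.69 (SE 0.15) and TAGLN at -3.58 (SE 0.15). Cell cycle genes fell too: in the mitosis list 0 rose and 36 fell of 42 (median -0.47, camera adjusted p = 1.40e-10, adjusted p = 0.143 with an estimated correlation), as with ANLN (-0.81 (SE 0.046)) and UBE2C (-0.84 (SE 0.056)). In the S phase list 2 rose and 29 fell of 43 (median -0.24, camera adjusted p = 0.0108, adjusted p = 0.262 with an estimated correlation). Among replication-dependent histones 0 rose and 13 fell of 15 (median -0.29, camera adjusted p = 0.0108, adjusted p = 0.450 with an estimated correlation).

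In the antigen presentation list 2 rose and 16 fell (2 and 18 adjusted over the list alone) of 26 (median -0.34, camera adjusted p = 5.36e-10, adjusted p = 0.143 with an estimated correlation). HLA-DRA was lower by 1128-fold (95% counting interval 311 to 9321) (fitted log2 value -9.84, and -9.26 without MITF overexpression replicate 1), HLA-DQA1 was at least 94.9-fold lower, and CIITA, the transactivator of class II genes, fell 47.8-fold. Reads of HLA-DRB1 and HLA-DRB5 are hard to tell apart, so their single values (143-fold lower for HLA-DRB1) are uncertain. Other lists that were called lower were endoplasmic reticulum chaperones (1 up and 19 down of 23, median -0.49, camera adjusted p = 7.69e-07, adjusted p = 0.209 with an estimated correlation), oxidative stress response (7 up and 19 down of 31, median -0.28, camera adjusted p = 0.00194, adjusted p = 0.272 with an estimated correlation) and heat shock response (1 up and 14 down of 20, median -0.24, camera adjusted p = 0.0363, adjusted p = 0.450 with an estimated correlation; camera adjusted p = 0.05001 without MITF overexpression replicate 2). Cholesterol and fatty acid synthesis was called higher (16 up and 3 down of 33, median 0.12, camera adjusted p = 0.00128, adjusted p = 0.425 with an estimated correlation), with SREBF1, a master regulator of lipid synthesis, at 1.12 (SE 0.067).

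The largest rises by the rule for named genes were in ADAMTS18 (at least 69.4-fold), ITIH5 (456-fold (95% counting interval 126 to 3769)), NOX5 (187-fold), PRDM7 (36.3-fold) and RELN (29.4-fold). The rule ranks fitted log2 values, so the place of a gene given only as a bound depends on the prior count. Among the largest falls by that rule outside the class II genes were HIST1H3I (at least 65.3-fold), AKR1E2 (at least 24.2-fold), TNIP3 (142-fold), PRRX1 (213-fold (95% counting interval 72.2 to 1037)) and MIPOL1 (176-fold (95% counting interval 30.8 to 7022)). Without MITF overexpression replicate 2 the fitted log2 values of PRRX1 (-7.54) and MIPOL1 (-6.93) became -8.32 and -8.58, and without MITF overexpression replicate 1 TNIP3 was 304-fold lower. In all, 8494 of 14297 genes changed, 4096 higher and 4398 lower, and 1738 of them changed at least 2-fold (865 higher and 873 lower). Camera called 19 of 35 lists, of which 9 were also called with an estimated correlation.

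Lists that were not called in this comparison were MITF family and neural crest regulators (9 up and 8 down of 19), MAPK pathway output (10 up and 12 down of 24), immediate early genes (15 up and 4 down of 24), interferon response (6 up and 2 down of 44), DNA repair (2 up and 14 down of 38), p53 targets (6 up and 18 down of 29) and apoptosis regulators (5 up and 9 down of 22). The same held for the TCA cycle (6 up and 4 down of 24), glycolysis and hypoxia (9 up and 16 down of 39), ATF4 and amino acid response (16 up and 8 down of 31, 16 and 9 adjusted over the list alone), ribosomal proteins (3 up and 18 down of 54, 3 and 17 adjusted over the list alone) and nuclear long non-coding RNAs (8 up and 1 down of 10). Leaving out 1 library started 2 calls. The immediate early list was called higher (camera adjusted p = 0.0251) without MITF overexpression replicate 1. The p53 list (camera adjusted p = 0.0505) was called lower without empty vector replicate 2 (0.0463) or 3 (0.0326) and without MITF overexpression replicate 1 (0.0396) or 2 (0.0474). In the list of MITF family and neural crest regulators, POU3F2 fell (-1.19 (SE 0.058)) and ETS1 rose (0.73 (SE 0.049)), and its median of 0.13 and mean of -0.28 differed in sign. Median and mean also differed in sign for oxidative phosphorylation (-0.0057 and 0.011), and the fibroblast list had a median of 0.33 with a test direction below 0.

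**Figure D2:**
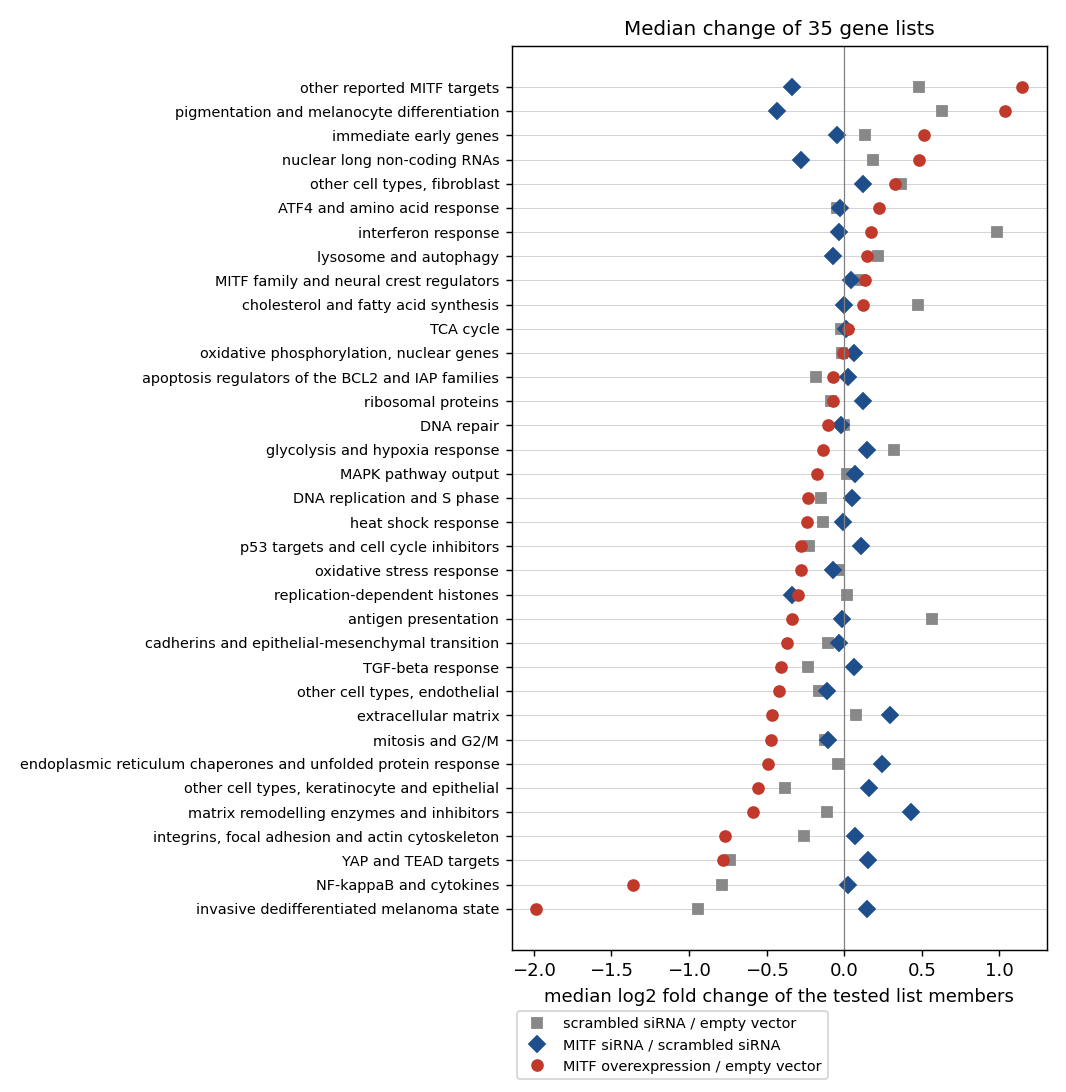
Median log2 fold change of the tested members of each of 35 gene lists, for MITF overexpression (circles), MITF siRNA (diamonds) and scrambled siRNA against the empty vector (squares). The pigmentation list lies at 1.03, -0.43 and 0.63 in these comparisons, and the invasive state list at -1.98, 0.14 and -0.94.

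The MITF overexpression libraries also stood apart in ways not limited to lists. A run of 57 neighbouring tested genes on chromosome 13, from SETDB2 to ABCC4, had a median log2 fold change of -0.54 (interquartile range -0.81 to -0.050), with 45 of its genes below 0. The same genes had medians of 0.019 with MITF siRNA and 0.018 between the control groups. All 11 tested Y-linked genes were called lower in this comparison, against 0 with MITF siRNA. The nuclear RNA MALAT1 took 1.22% to 1.27% of the counts in these libraries and 0.273% to 0.758% in the other 9. These differences ran alongside the changes of every gene group described above.

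**Figure D3:**
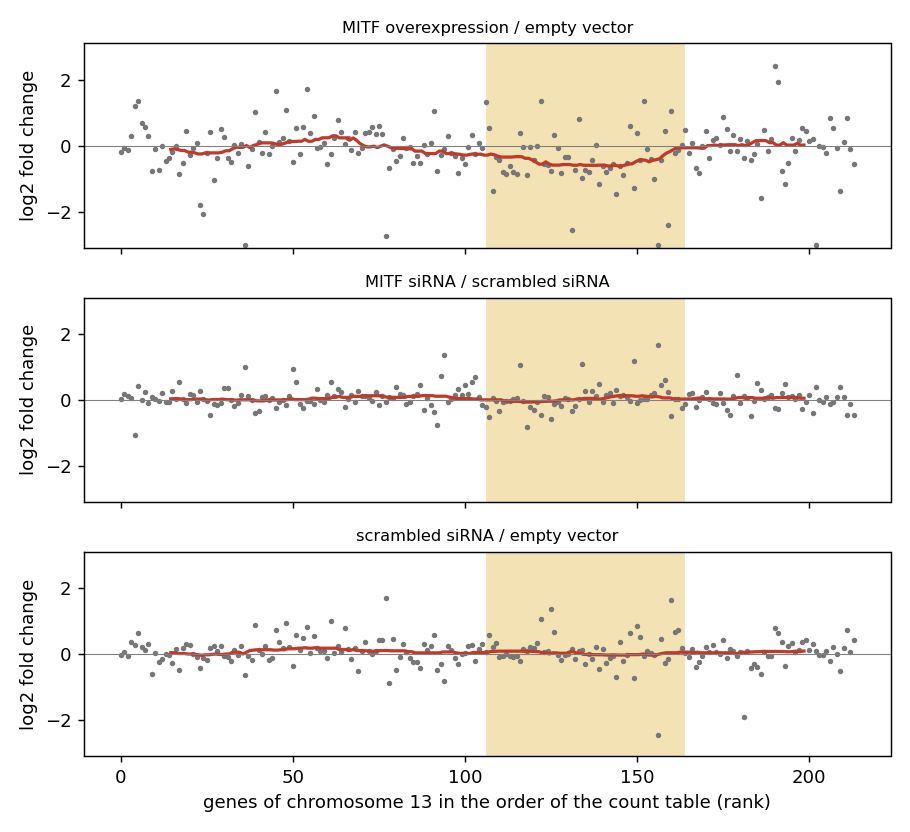
Log2 fold change of each tested gene of chromosome 13 (points, those beyond 3 drawn at 3) in the order of the count table, in the 3 comparisons, with the median over 30 neighbouring genes as a line. The shaded run of 57 genes lies at a median of -0.54 with MITF overexpression, 0.019 with MITF siRNA and 0.018 between the control groups.

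The comparison of MITF siRNA with scrambled siRNA asks what a lowered MITF level does. Effects of the siRNA on genes other than MITF cannot be told apart from effects of lowered MITF with these libraries. With MITF 26.4% lower, pigment genes fell and genes of the extracellular matrix and its remodelling rose. None of these 3 lists was called with an estimated correlation (adjusted p = 0.0890, 0.0626 and 0.0928). MLANA fell 1.83-fold (from 110.0 ± 7.41 to 59.9 ± 4.64 CPM, n = 3 per group, adjusted p = 1.12e-13). MMP15, a membrane-anchored metalloproteinase, rose 3.21-fold (adjusted p = 1.35e-22). The changes were smaller than with overexpression, with a median absolute log2 fold change among called genes of 0.30 against 0.45.

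In the pigmentation list 0 rose and 13 fell (0 and 14 adjusted over the list alone) of 19 (median -0.43, camera adjusted p = 8.52e-11, adjusted p = 0.0890 with an estimated correlation), including GPNMB (-0.55 (SE 0.043)), CAPN3 (-0.79 (SE 0.063)) and SLC45A2 (-0.52 (SE 0.055)). Among other reported MITF targets 1 rose and 22 fell of 28 (median -0.33, camera adjusted p = 8.52e-11, adjusted p = 0.0928 with an estimated correlation), with RRAGD at -0.64 (SE 0.056), the transcription factor gene IRF4 at -0.69 (SE 0.061) and ASAH1 at -0.46 (SE 0.045). The lysosome and autophagy list was called lower (5 up and 22 down of 56, median -0.074, camera adjusted p = 0.00118, adjusted p = 0.313 with an estimated correlation), for instance SQSTM1 (-0.61 (SE 0.048)).

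In the extracellular matrix list 20 rose and 2 fell (22 and 2 adjusted over the list alone) of 35 (median 0.29, camera adjusted p = 3.40e-10, adjusted p = 0.0626 with an estimated correlation), among them VCAN (1.16 (SE 0.057)), the laminin gene LAMA4 (1.01 (SE 0.050)) and COL5A2 (3.04-fold). Matrix remodelling genes had 16 up and 2 down of 25 tested (median 0.43, camera adjusted p = 1.88e-13, adjusted p = 0.0928 with an estimated correlation), with LOXL3 at 1.45 (SE 0.082) and ADAMTS1 at 0.85 (SE 0.053). YAP and TEAD targets were called higher (10 up and 2 down of 25, median 0.16, camera adjusted p = 0.00118, adjusted p = 0.422 with an estimated correlation), with CTGF at 1.24 (SE 0.093). The prostaglandin synthase gene PTGS2 rose 3.32-fold in the NF-kappaB and cytokine list (8 up and 3 down of 28, 9 and 3 adjusted over the list alone, median 0.027, camera adjusted p = 0.0408, adjusted p = 0.714 with an estimated correlation), a call that ended without scrambled siRNA replicate 1 (adjusted p = 0.415, median -0.035). Endoplasmic reticulum chaperones (13 rose and 2 fell (14 and 4 adjusted over the list alone) of 23, median 0.24, camera adjusted p = 1.88e-04, adjusted p = 0.635 with an estimated correlation) and ribosomal proteins (28 rose and 1 fell (30 and 1 adjusted over the list alone) of 54, median 0.12, camera adjusted p = 0.00118, adjusted p = 0.744 with an estimated correlation) were called higher.

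The list of MITF family and neural crest regulators was not called (8 up and 5 down of 19, median 0.042, camera adjusted p = 0.102, adjusted p = 0.635 with an estimated correlation). Of its members, FOXD3 rose 2.08-fold, SOX2 rose (log2 fold change 1.32 (SE 0.12)) and POU3F2 rose 1.48-fold, while SNAI2 fell (-0.41 (SE 0.054)). The invasive state list had 6 up and 3 down of 20 tested and was not called (camera adjusted p = 0.230). FGF2 rose (0.95 (SE 0.074)) and LOXL2 fell (-0.93 (SE 0.16)). All 15 tested replication-dependent histone genes fell (median -0.34, camera adjusted p = 3.21e-10, adjusted p = 0.178 with an estimated correlation), as 13 did with overexpression. Mitosis genes were called lower (2 rose and 18 fell (2 and 19 adjusted over the list alone) of 42, median -0.10, camera adjusted p = 0.00786, adjusted p = 0.714 with an estimated correlation). Glycolysis and hypoxia genes were called higher (16 rose and 4 fell (18 and 4 adjusted over the list alone) of 39, median 0.15, camera adjusted p = 0.00786, adjusted p = 0.780 with an estimated correlation). Oxidative stress genes were called lower (3 up and 13 down of 31, median -0.071, camera adjusted p = 0.0187, adjusted p = 0.635 with an estimated correlation). Leaving out MITF siRNA replicate 3 ended the mitosis (camera adjusted p = 0.0535) and oxidative stress (0.0715) calls. The glycolysis call ended without MITF siRNA replicate 2 (0.0771) or scrambled siRNA replicate 1 (0.0748). The invasive state list was called higher without MITF siRNA replicate 3 (0.0481) or scrambled siRNA replicate 3 (0.0347), and MAPK pathway output without the same libraries (0.0481 and 0.0260). Oxidative phosphorylation was called without scrambled siRNA replicate 1 (0.0482).

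Among the largest rises were those of DENND2A (6.12-fold, adjusted p = 4.33e-15), SCRG1 (5.49-fold), AFAP1L2 (5.32-fold) and COL5A3 (4.11-fold). The largest falls were in IGFN1 (4.01-fold), KU-MEL-3 (3.47-fold), PRDM7 (2.87-fold), CDH23 (2.73-fold) and TRIM63 (2.44-fold). In all, 5057 genes changed, 2673 higher and 2384 lower, of which 251 changed at least 2-fold (188 higher and 63 lower). Camera called 13 of 35 lists, and with an estimated correlation 0 were called after adjustment and 5 at an unadjusted p under 0.05, against 18 by fry. The other 22 lists were not called with all libraries.

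Whether the same genes answer in opposite ways to the MITF vector and to the MITF siRNA was asked across all tested genes. The 2 comparisons share no libraries. Genes changed in both comparisons numbered 3529, and 2538 of them (71.9%) changed in opposite directions, against 1505 for independent lists. Of these, 1109 rose with overexpression and fell with siRNA, as MLANA, SLC45A2, ASAH1 and PRDM7 did. The other 1429 fell with overexpression and rose with siRNA, as VCAN, FGF2, LOXL3, MMP15, POU3F2, CDH2 (0.47 (SE 0.052) with siRNA) and BIRC3 (0.70 (SE 0.068) with siRNA) did. Changes in the same direction numbered 991, against 1499 for independent lists, and they included histone genes such as HIST1H2BC (-0.42 (SE 0.051) and -0.46 (SE 0.051)). Among genes changed at least 2-fold in both, 120 moved in opposite and 24 in the same direction. Across genes, which are not independent replicates, the log2 fold changes had a Spearman's rho of -0.28.

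The test of the difference between the responses called 8134 genes, 3879 with a higher and 4255 with a lower log2 fold change under overexpression than under siRNA. MITF itself differed by 1.56 (SE 0.072). Exchanging the control groups moved the picture: against the empty vector, the MITF siRNA libraries had medians of 0.14 in the pigmentation list and 0.14 in the list of other MITF targets, above 0 in place of below.

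**Figure D4:**
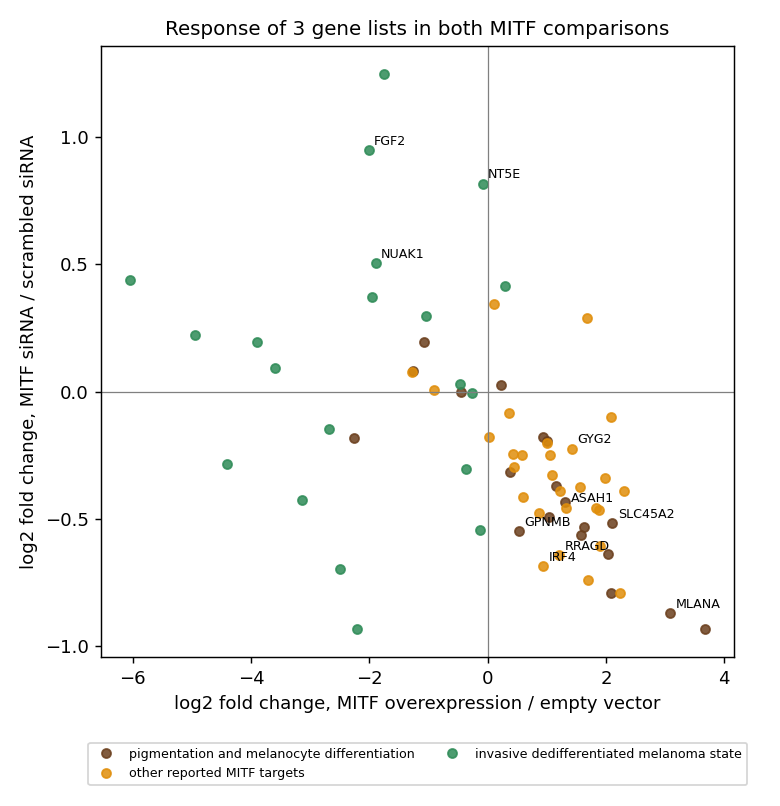
Log2 fold changes with MITF overexpression (x axis) and MITF siRNA (y axis) of the tested members of 3 gene lists, 1 point per gene. Pigmentation genes and other MITF targets gather at the lower right (MLANA at 3.08 and -0.87), and TYRP1, at -1.26 on the x axis, lies to the left.

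The control groups were compared with each other to see what separates siRNA-treated from vector-transduced cells. Interferon-induced genes were higher in the scrambled siRNA libraries: 40 were higher and 0 were lower (41 and 0 adjusted over the list alone) of 44 (median 0.99, camera adjusted p = 5.70e-14, adjusted p = 0.306 with an estimated correlation). IFI27 was higher by 298-fold (95% counting interval 102 to 1449.6), IFITM1 96.0-fold, BST2 27.0-fold, IFI6 13.0-fold and MX1 9.11-fold (adjusted p = 0.00334). Without scrambled siRNA replicate 3, which had the highest mean level of the list, BST2 was 18.0-fold and IFITM1 57.4-fold higher, and the fitted log2 value of IFI27 (8.10) became 7.17; without empty vector replicate 3 it became 9.05. The mean log2 level of the list, relative to the empty vector mean, ran from 0.97 to 2.11 in the scrambled siRNA libraries, so that the libraries of this group differed among themselves. It was 1.47, 1.69 and 1.61 in the MITF siRNA libraries and 0.063, 0.067 and 0.049 in the MITF overexpression libraries. Between the siRNA groups the list was not called (median -0.034), and leaving out 1 library gave calls in opposite directions: median -0.22 (camera adjusted p = 0.0134) without scrambled siRNA replicate 1 and 0.21 (0.00324) without scrambled siRNA replicate 3.

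**Figure D5:**
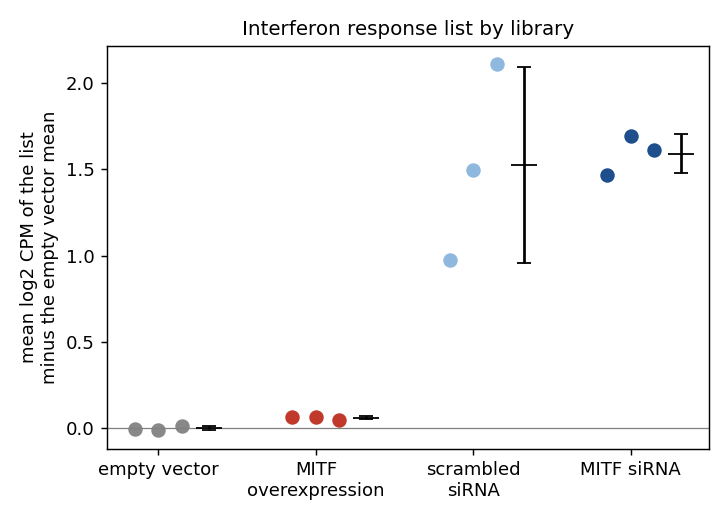
Mean log2 CPM of the 44 tested interferon response genes in each library, minus the mean of the empty vector libraries, 3 points per group with the group mean and SD. The scrambled siRNA libraries run from 0.97 to 2.11 and the MITF siRNA libraries from 1.47 to 1.69.

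Antigen presentation genes were also higher with scrambled siRNA (20 were higher and 1 were lower of 26, median 0.57, camera adjusted p = 1.64e-12, adjusted p = 0.117 with an estimated correlation), for example HLA-DPA1 (1.14 (SE 0.070)). So were pigmentation genes (15 were higher and 1 were lower (16 and 1 adjusted over the list alone) of 19, median 0.63, camera adjusted p = 3.48e-15, adjusted p = 0.0342 with an estimated correlation), with MLANA at 0.83 (SE 0.060) and TYR, the tyrosinase gene, at 0.55 (SE 0.045). Other MITF targets (21 up and 3 down of 28, 22 and 4 adjusted over the list alone, median 0.48, camera adjusted p = 4.75e-12, adjusted p = 0.05003 with an estimated correlation), lysosomal genes (36 up and 6 down of 56, 38 and 6 adjusted over the list alone, median 0.21, camera adjusted p = 2.38e-06, adjusted p = 0.05003 with an estimated correlation), cholesterol and fatty acid synthesis (27 up and 0 down of 33, median 0.47, camera adjusted p = 3.60e-21, adjusted p = 0.05003 with an estimated correlation) and glycolysis and hypoxia genes (25 up and 1 down of 39, median 0.32, camera adjusted p = 7.61e-07, adjusted p = 0.405 with an estimated correlation) were called higher. HMGCS1, an enzyme of cholesterol synthesis, was at 0.82 (SE 0.048).

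Lower with scrambled siRNA were NF-kappaB and cytokine genes (2 up and 21 down of 28, 3 and 21 adjusted over the list alone, median -0.79, camera adjusted p = 2.72e-18, adjusted p = 0.0418 with an estimated correlation), YAP and TEAD targets (0 up and 17 down of 25, median -0.73, camera adjusted p = 5.70e-14, adjusted p = 0.0342 with an estimated correlation) and the invasive state list (2 up and 15 down of 20, median -0.94, camera adjusted p = 1.91e-10, adjusted p = 0.0818 with an estimated correlation). AXL, a receptor kinase of that state, was at -1.70 (SE 0.12), NUAK1 at -1.64 (SE 0.11), CYR61 at -1.30 (SE 0.086) and IL6 at -1.90 (SE 0.14). Integrin and actin genes were lower too (4 up and 29 down of 43, median -0.26, camera adjusted p = 7.85e-13, adjusted p = 0.0985 with an estimated correlation). Also called lower, with the adjusted p at an estimated correlation in brackets, were matrix remodelling (4 up and 11 down of 25, 5 and 11 adjusted over the list alone, 0.405), cadherins (3 up and 7 down of 16, 3 and 8 adjusted over the list alone, 0.05003), TGF-beta response (3 up and 11 down of 25, 0.306), S phase (4 up and 20 down of 43, 4 and 22 adjusted over the list alone, 0.221), mitosis (4 up and 20 down of 42, 5 and 21 adjusted over the list alone, 0.530), p53 targets (5 up and 15 down of 29, 0.134), apoptosis regulators (4 up and 10 down of 22, 0.172), heat shock response (1 up and 10 down of 20, 1 and 11 adjusted over the list alone, 0.463) and ribosomal proteins (1 up and 23 down of 54, 1 and 24 adjusted over the list alone, 0.771). The p53 call ended without empty vector replicate 1 (camera adjusted p = 0.0674). The extracellular matrix list was not called, with a median of 0.078 and a mean of -0.20. The largest falls were in SMOC1 (6.44-fold), PTRF (6.33-fold), THBS1 (5.64-fold), SLITRK6 (5.49-fold) and IL11 (5.32-fold). In all, 5502 genes differed between the control groups, 2706 higher and 2796 lower with scrambled siRNA. Camera called 20 of 35 lists and 3 with an estimated correlation. The vector and siRNA cultures differ in virus, selection and transfection, and no library links them, so these cannot be separated here.

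Most markers of immune, endothelial (5 of 15 tested) and keratinocyte and epithelial cells (5 of 20) did not pass the filter, whereas 10 of 19 fibroblast markers did. Of 20 immune markers, 3 passed the filter (CD68, LYZ and ITGAM) and 7 had no count in any library. With overexpression ITGAM rose (2.33 (SE 0.27)) and LYZ fell (-2.36 (SE 0.31)). The endothelial (1 up and 1 down of 5 with overexpression, 1 up and 0 down of 5 with siRNA), keratinocyte and epithelial (1 up and 4 down of 5 and 2 up and 1 down of 5, 3 and 1 adjusted over the list alone) and fibroblast (3 up and 2 down of 10 and 2 up and 0 down of 10) marker lists were not called in either MITF comparison. No gene of the list of mitochondrially encoded genes was in the table used here.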

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

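The tests in this part were chosen after the result was seen, apart from the tests of other splits of the libraries and the test of the difference between responses.

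10 genes stood out because their response to MITF overexpression differed most from their response to MITF siRNA, as log2 differences of the 2 fold changes (edgeR quasi-likelihood test, adjusted p at most 2.46e-04). Higher under overexpression were ITIH5 at 9.42 (SE 0.80), ADAMTS18 at 9.09 (SE 2.0), NOX5 at 8.23 (SE 0.68), PRDM7 at 6.71 (SE 0.37) and LINC01531 at 6.62 (SE 0.46). Lower were HLA-DRA at -9.86 (SE 0.32), HLA-DQA1 at -9.23 (SE 0.58), HIST1H3I at -8.62 (SE 0.66), HLA-DRB5 at -8.52 (SE 0.41) and AKR1E2 at -7.87 (SE 0.79). With MITF siRNA itself HLA-DRA (0.015), HLA-DQA1 (-0.068) and HLA-DRB5 (0.17) were not called, whereas PRDM7 fell. The differences of these class II genes therefore restate their change with overexpression. Several of the 10 genes are near 0 in 1 group, so the fitted sizes depend on the prior count and are no bounds. Without MITF overexpression replicate 1 HLA-DRA was at -9.26 and HLA-DRB5 at -10.15, and without scrambled siRNA replicate 2 ADAMTS18 was at 8.27.

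All 3 MITF overexpression libraries shared features that the other 9 lacked: a run of neighbouring genes on chromosome 13 was lower, 13 of 15 HLA class II genes were lower, all 11 tested Y-linked genes were called lower (against 0 with MITF siRNA and 0 between the controls, where 1 and 8 were higher), and 11 genes outside the Y chromosome (3 of them among the class II genes just counted) lay under 0.1 CPM in all 3 while above 2 CPM in every other library, against 0 such genes in any other group. 2 genes showed the reverse, near 0 in every library but these 3. The cut of 0.1 CPM is on measured values: at the floor of 3 counts, a count of 0 allows up to 0.141 to 0.204 CPM in the overexpression libraries. It is stricter for the empty vector group, whose shallowest library resolves 0.404 CPM. For the class II and Y-linked genes the values argue against a change in proportion to the MITF transcript. MITF was higher with scrambled siRNA than with the empty vector, so proportion would make them lower there. Instead 15 class II genes were higher and 0 lower (median 0.98), and 0 Y-linked genes were lower. With MITF siRNA 7 class II genes rose and 0 fell, the direction of proportion, but their median was 0.17 against -5.58 with overexpression. The control groups also differ in handling, and 40 of 44 interferon response genes were higher with scrambled siRNA. The class II rise between the controls therefore cannot decide on proportion. Both siRNA groups were transfected, so the values with MITF siRNA weigh more: MITF was at -0.44 there against 1.11 with overexpression. In proportion, lower MITF would raise the Y-linked genes there, yet 1 of 11 was called higher. For the run the question stays open. It was picked for being low, so no size can be derived from it. Its median of 0.018 between the control groups also carries their other differences. 2 tests against scaling of the libraries were void and are not used: an interval over the run's own genes, which had been picked for being low, and the lowest median over 30 neighbours less the median of all genes (-0.60), since 1 factor per library moves real and shuffled gene orders alike. A candidate explanation is that the overexpression cells have another genetic makeup, for example a subclone with a lost chromosome segment: the lowest median over 30 neighbours was -0.62 against -0.50 in 1000 shuffled gene orders, although medians beyond the shuffles were also seen between the control groups, at a zinc finger gene cluster and the HLA region. A MITF effect remains open too, but for the class II and Y-linked genes not in proportion to the transcript. The part of the overexpression changes that belongs to MITF cannot be separated from such a background with these libraries.

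Interferon response genes were higher in both siRNA groups than with the empty vector, by a median log2 difference of 0.98 with MITF siRNA and 0.99 with scrambled siRNA. In proportion to the MITF transcript the list would reach 1.77 with overexpression. Its median there was 0.17 (95% bootstrap interval over its genes 0.025 to 0.26). That interval treats genes that move together (estimated correlation 0.69) as independent and does not measure the spread between libraries. By overexpression library the median was 0.13, 0.20 and 0.13 relative to the empty vector mean. These values argue against proportion as the whole cause, although the median of 0.17 was not 0 or below as the test had put it. Immune cells as a source stay open: the test first made, on the summed immune list, gave 19.9 to 25.5 CPM in the siRNA and 13.6 to 16.9 CPM in the empty vector libraries, over its limit of 1 CPM and mostly from CD68. It was then replaced by PTPRC alone, which reached at most 0.441 CPM, too near the floor to exclude such cells. The list sum cannot decide, as it rests mostly on 1 marker, CD68. It was 20.7 to 28.5 CPM in the overexpression libraries, and CD68 gave 364 of 538, 379 of 582 and 223 of 314 counts. There the interferon list lay only 0.063, 0.067 and 0.049 above the empty vector. A value that goes against immune cells is that 7 of 20 markers, TYROBP and CD3E among them, had no count in any library. A response to siRNA delivery may account for the rise, and it cannot be told apart from any other difference between the transfected and the transduced cultures.

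MITF was higher with scrambled siRNA than with the empty vector, and its target lists with it. The log2 difference was 0.62 to 0.63 under TMM, DESeq2 size factors, upper quartile and library totals, but the alternatives to TMM moved the median gene by at most 0.010, so they do not test scaling of the libraries. Different handling of the cultures, such as selection of transduced cells, may underlie the difference of 0.62, but handling and group cannot be told apart in this design.

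Other splits of the 6 libraries called 0 genes in the overexpression comparison (real value 8494), the siRNA comparison (5057) and that of the controls (5502), the real split being 1 of 10 in each, and 10 splits are too few for a share under 0.05. For lists called by camera the highest other split gave 19 against 19, 15 against 13 and 16 against 20, and 2, 4 and 1 of the 10 splits gave as many lists. Each of these splits sets 2 libraries of a group against 1 and so keeps part of the group difference. The counts of lists therefore say little by themselves. Among 40 joint splits of both pairs, 1, the real one, gave as many, both for genes with differing responses (8134, highest other 5023) and for opposite changes (2538, highest other 0, 1 of 40 as many). The splits say nothing on either count, as no other split called genes in both comparisons.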

How the results depend on the processing

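The exchange of control groups was chosen after seeing the data, and the other alternatives beforehand. The counts of called genes stayed within 1.5 times their value under every change of test, scaling, filter or library; leaving out 1 library gave 7662 to 8251 for overexpression and 4119 to 4741 for siRNA. The balance of directions turned with scaling: upper-quartile scaling gave 2176 higher and 2881 lower genes for siRNA, and library totals 4841 and 3699 for overexpression. For the difference of responses they were 4565 and 3615 under upper-quartile scaling and 4690 and 3455 under library totals. A threshold of at least 2-fold left 1738, 251 and 589 genes. With an estimated correlation 9, 0 and 3 lists were called, and fry called 30 for overexpression. Over the 3 comparisons limma-voom ended 4 list calls and started 3, and no filter on low counts ended 2 and started 6. Only the libraries compared ended 2 and started 2, and a replicate block within each comparison ended 2 and started 4. Library totals ended 1, while DESeq2 size factors and library sizes without the 20 most abundant genes each started 1. The block within each comparison also ended 2 calls of named genes. The correlation of the responses was -0.166 with no filter on low counts, and -0.33 to -0.20 with 1 library left out (without MITF siRNA replicate 3 and without MITF siRNA replicate 2). The interferon list between the siRNA groups went to -0.22 without scrambled siRNA replicate 1 and reversed to 0.21 without scrambled siRNA replicate 3.

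With the other control group (overexpression against scrambled siRNA, MITF siRNA against the empty vector), MITF in the siRNA comparison reversed to 0.178, the correlation was -0.0719 and same-direction changes numbered 1568. Lists whose test direction turned, with a call under at least 1 of the controls, are given with their medians. For overexpression they were interferon at -1.03 and cholesterol synthesis at -0.28. For MITF siRNA they were pigmentation at 0.14, other MITF targets at 0.14, the invasive state at -0.65, integrins at -0.31, cadherins at -0.026, lysosome at 0.11, YAP targets at -0.36, interferon at 0.98, NF-kappaB at -0.60, antigen presentation at 0.54, apoptosis at -0.12 and cholesterol synthesis at 0.52. These follow from the exchange itself, as the controls differ in 5502 genes. Of the siRNA calls, 2552 remained in direction and 476 turned, and of the overexpression calls 5329 and 281. Of the genes named for siRNA, those that reversed were ADAMTS1 at -0.28, BIRC3 at -0.69, CAPN3 at 0.24, CDH2 at -0.29, CTGF at -0.37, GPNMB at 0.042, KU-MEL-3 at 0.39, POU3F2 at -0.13 and SNAI2 at 0.040.

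The replicate numbers do not pair the libraries: deviations of same-numbered libraries from their group means correlated at -0.12 to 0.064 over all pairs of groups. With a replicate block over the 12 libraries 8408, 4960 and 5394 genes were called. Depth limits genes near the floor, where the shallowest library (empty vector replicate 2) resolves 0.404 CPM.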

Other observations

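The test in this part was chosen after the result was seen. HLA class II genes and their regulators, a group picked after its values were seen, gave 15 tested genes (some of them near-identical family members), of which 13 fell and 1 rose with MITF overexpression. With MITF siRNA 7 rose and 0 fell, and 15 were higher with scrambled siRNA than with the empty vector. CD74, the invariant chain, was at -6.65 (SE 0.17) with overexpression, 0.24 (SE 0.076) with MITF siRNA and 0.90 (SE 0.084) between the controls; the siRNA call ended without MITF siRNA replicate 1 (adjusted p = 0.0639), MITF siRNA replicate 2 (0.0914), scrambled siRNA replicate 1 (0.0650) or scrambled siRNA replicate 2 (0.0611). HLA-DOB, an inhibitor of peptide loading, was the gene that rose with overexpression (3.03-fold), and HLA-DPB1 was at -0.15 (SE 0.067) (adjusted p = 0.0577, edgeR quasi-likelihood test, and 0.0414 without empty vector replicate 1).

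Between MITF siRNA and the empty vector, a comparison the design does not name, 6103 genes were called, 3123 higher and 2980 lower with MITF siRNA. Cholesterol and fatty acid synthesis had 26 higher and 0 lower of 33, and glycolysis and hypoxia 30 and 3 of 39.

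The small RNA gene MIR6087 took 1.17% and 1.26% of the counts in empty vector replicates 2 and 3, 0.0416% in replicate 1 and at most 0.0803% in the other groups. MITF siRNA replicate 2 had the lowest share of MALAT1 (0.273%) and of NEAT1 (0.0805%) among the 12 libraries.

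A hypothesis is that genes of the MITF target lists follow the MITF transcript over all 4 groups, in the order empty vector, MITF siRNA, scrambled siRNA, MITF overexpression. Of 47 tested genes of the pigmentation list and the list of other targets, 22 (46.8%) had group means in that order, against 1363 of 14249 other genes (9.57%). In large part this order restates the calls of the lists in the 3 comparisons, so the share is no test of its own. The mean log2 level of the pigmentation list, relative to the empty vector, was 0.17 ± 0.050 with MITF siRNA, 0.55 ± 0.094 with scrambled siRNA and 0.99 ± 0.044 with overexpression (SD, n = 3). Whether the relation is graded stays open, as the groups also differ in handling.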
